A study of Sus scrofa with 9 samples.

How the data were processed

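Adipose tissue of pigs (Sus scrofa) was profiled by droplet-based single-cell RNA sequencing; the labels do not name the fat depot. The series holds 9 samples. There are 3 from germ-free pigs (GF, raised without microbes), 3 from human-flora-associated pigs (HFA, germ-free pigs given microbes of human origin) and 3 from specific pathogen-free pigs (SPF, which carry microbes but no listed pathogens). Per the labels' protocols, minced tissue was digested with trypsin and DNase, strained, treated to lyse red blood cells, and loaded with barcoded beads that tag the 3' ends of messages with unique molecular identifiers (UMIs). Samples are numbered as in their label descriptions (GF 1, GF 2 and GF 3, and likewise for HFA and SPF). The sample titles differ: they number the HFA samples 1, 3 and 4 and the SPF samples 2, 3 and 5, in the same order, so that at most 2 samples of any 2 groups share a number by title. Which numbering belongs to the animals is not known.

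The deposited values are raw UMI counts per gene and cell barcode, made with Cell Ranger 6.0.1 per the file headers and the submitters' processing notes. The genome build was Sscrofa11.1 per the submitters' processing notes. The annotation release is not stated and the files give no gene positions, so genes are identified by symbol and gene identifier alone. The deposited barcodes had been filtered, and none had fewer than 500 UMIs. The gene tables of the 9 samples list 21303 features, of which 6417 have no symbol. A reference table of gene names gave symbols for 664 of these, a step added after the first clusters were seen.

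Barcodes were kept with at least 300 genes, at least 500 UMIs and at most 20% of UMIs from the 13 mitochondrially encoded genes. Of 89655 barcodes, 89581 passed. Doublets were scored per sample with scrublet in scanpy 1.11.5, and the highest-scoring 0.8% of cells per 1000 barcodes of a sample were removed, 7350 cells in all, which left 82231. Genes seen in at least 10 cells were kept, 18205 in number. Counts were scaled to 10000 per cell and logged. Leiden clustering (leidenalg 0.10.2, resolution 1.0) on 2000 variable genes, 30 principal components and 15 neighbours, without integration, gave 37 clusters. Clusters were named from marker genes fixed beforehand, by a score over those markers. Of the clusters, 30 were named and fell into 12 classes with 74061 cells, and 7 with 8170 cells (9.94%) stayed unnamed. The score was written with the data in hand, and its conditions for clusters of low or high UMI counts were added after the first names were seen.

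Raw counts were summed per sample and class, since the animal and not the cell is the replicate. Samples with fewer than 20 cells of a class were left out, and a comparison was made where both groups kept at least 2 samples. Genes were tested with edgeR 4.0.16 (TMM factors, filterByExpr by group, robust quasi-likelihood F-test), with 1 fit per class over all 9 samples. P values were adjusted over genes by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are log2 values ± standard error (SE). Where a median over a set of genes is given, ± is the SD over those genes and not a spread between samples. Expression levels are CPM (counts scaled to the same total in every sample and class), as mean ± SD over the 3 samples of a group. Cell shares were tested with the same edgeR test on cell numbers of the 12 classes, each with at least 50 cells, and with exact permutation tests, all two-sided. An exact test of 3 against 3 samples cannot go below 0.10. Gene lists, 34 in number, were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, where at least 5 members were tested. This left 31 or 32 lists in each main class. The estimated correlation and fry were tried beside it. Both depend slightly on the order in which samples enter the model. In the first order rounding moved them between 2 equal runs, so the model was rewritten, after these values had been seen, in a form and order without that instability. In the main classes fry kept fewer of the calls after that (8 of 76), and an estimated correlation kept 0 before and after. The main classes are the 3 with the most cells: adipose stem and progenitor cells (called progenitors), adipocytes and endothelial cells. Sample groups, tests, gene lists, markers, filters, the rule for named genes and all alternatives except those said to be added were fixed before the data were examined.

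The rule for named genes takes, per comparison and main class, genes past the threshold in which every sample of one group lies above every sample of the other. Of these it names up to 5 with the largest rise and up to 5 with the largest fall. Genes with no symbol, with a mean under 10 counts, or of the haemoglobin, immunoglobulin and sex-linked sets are passed over. Where fewer than 3 genes pass, the 3 with the smallest p are given as values. Up to 4 members with the smallest p are added for each list that passes camera or has 3 or more members past the threshold, as is a fixed panel of marker and immune genes. Genes outside this rule, among them HBB, WT1 and the genes of mural and other classes, were chosen after their values were seen.

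For genes, the alternatives were DESeq2 size factors in edgeR, the DESeq2 1.42.0 Wald test, limma voom, no filter on low counts, only the 6 samples compared, the replicate number as a block, each sample left out in turn, doublets kept, a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial), classes from resolution 2.0, equal cell numbers, and an added minimum absolute log2 fold change of 1. Shares and lists were recomputed under those that apply to them. Leaving out HFA 2 and SPF 3 together, counting an unnamed cluster led by WT1 with the progenitors, and DESeq2 size factors in the list tests were added after the clusters were seen.

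The tests were tried on simulated counts. For SPF against GF, absolute log2 fold changes of 2 were found in 86% of the changed genes in progenitors, 66% in adipocytes and 84% in endothelial cells. Absolute log2 fold changes of 1 were found in 12%, 15.2% and 31%. False calls numbered 7, 4 and 4. A doubled mural share in SPF against GF was found in 35 of 50 simulations, with 0 false calls, at a dispersion of 0.05. In the real data the SE of the share difference was 0.30 in mural cells and 0.56 in progenitors. The rate found for mural cells thus does not carry over to classes that vary more.

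Some decisions on the technical explanations in the closing section were changed after their values were seen. The bound set beforehand for free RNA as the source of the ribosomal protein difference was met, but that explanation was left open because of HBB. The bound for another fat depot was at first read without its spread. The test of free muscle RNA in adipocytes of HFA 2 did not decide, and another, on endothelial cells, was added. Its outcome turned with clusters of resolution 2.0, which were tried last, so that explanation was left open. The mesothelial test gained the condition that its markers be detectable in some class, which did not change its outcome. The software also included Python 3.11.15, anndata 0.12.19, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and its data.table package (1.17.8).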

Results

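Single-cell expression was measured in 9 samples of pig adipose tissue, 3 GF, 3 HFA and 3 SPF. Fat of animals without microbes can thus be set beside fat of animals with human-derived microbes or those of SPF pigs. No label gives a litter or batch, so such differences between the groups cannot be told apart from microbial status in any comparison. Total depth was 49738764, 49232456 and 64238243 UMIs in GF 1, GF 2 and GF 3. It was 49504151, 65066784 and 70665558 UMIs in HFA 1, HFA 2 and HFA 3, and 64250040, 61926416 and 65942837 UMIs in SPF 1, SPF 2 and SPF 3. Kept cells numbered 7278, 8133 and 10000 in the GF samples, 6318, 10069 and 10739 in the HFA samples, and 9954, 9345 and 10395 in the SPF samples. Median UMIs per kept cell lay between 4062 (SPF 3) and 5795 (HFA 1). The median percent of UMIs from mitochondrially encoded genes lay between 0.0371 (GF 1) and 0.214 (HFA 2).

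Progenitors, the cells that can become adipocytes, were the class with the most cells, with 39.3% ± 1.90 of kept cells in GF, 40.4% ± 9.60 in HFA and 29.7% ± 18.7 in SPF (mean ± SD, n = 3). SPF 3 held 8.20%, with a further 26.6% of its cells in cluster 7, a group with progenitor markers left unnamed. Counting that cluster, SPF 3 held 34.8% and the SPF mean was 38.6% ± 3.46. Adipocytes made up 19.5% ± 1.27, 22.6% ± 9.22 and 27.0% ± 8.52, and endothelial cells 9.37% ± 0.849, 10.2% ± 2.47 and 12.6% ± 1.66. Macrophages or monocytes took 8.27% ± 1.65 of GF, 6.63% ± 2.84 of HFA and 4.56% ± 1.71 of SPF cells, and mural cells of vessel walls took 6.51% ± 0.526, 5.71% ± 2.19 and 4.28% ± 0.358. Lymphatic endothelial cells were at 4.69% ± 0.132, 4.53% ± 1.14 and 2.41% ± 1.76, cycling cells at 1.16% ± 0.424, 1.94% ± 0.428 and 0.692% ± 0.153, and T or NK cells at 0.875% ± 0.417, 0.542% ± 0.392 and 1.40% ± 0.804. Schwann cells were at 1.03% ± 0.307, 0.706% ± 0.187 and 0.525% ± 0.0952.

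**Figure D1:**
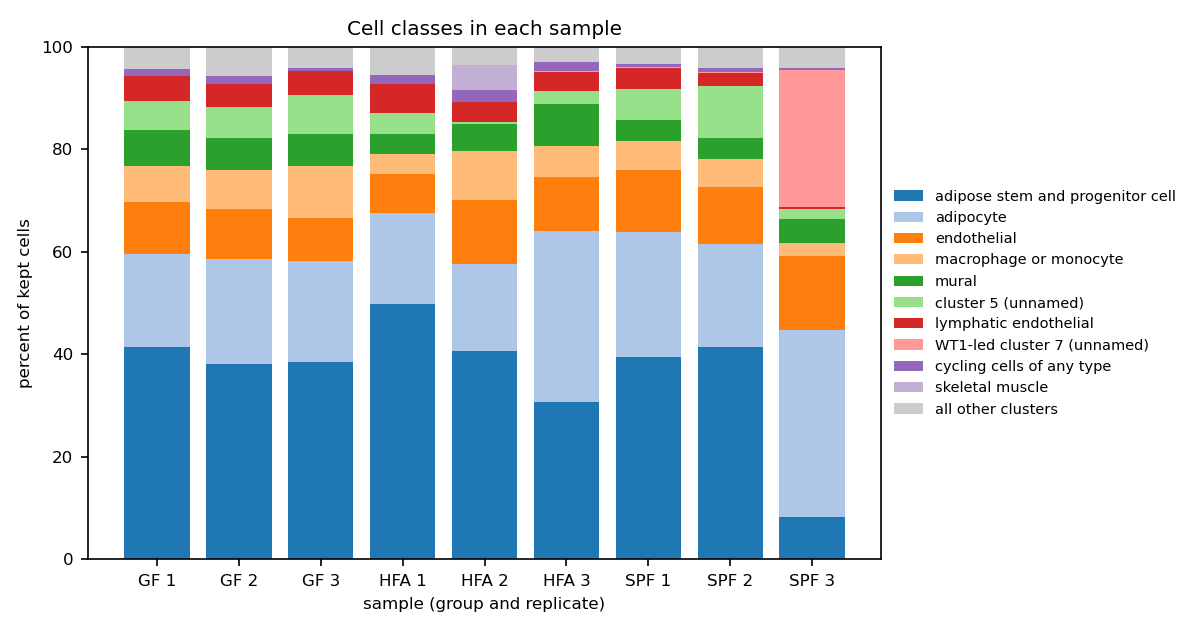
Percent of kept cells per class (stacked bars) in each of the 9 samples. SPF 3 holds 8.20% progenitors, against a GF mean of 39.3%, and 34.8% with the unnamed cluster 7 counted.

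No class share passed the edgeR test on cell numbers in any of the 3 comparisons. The counts at an unadjusted p under 0.05 were 0 of 12 classes for HFA against GF, 1 for SPF against GF (Schwann cells, log2 fold change -0.97 ± 0.33, adjusted p = 0.244) and 1 for SPF against HFA (cycling cells, -1.48 ± 0.37, adjusted p = 0.0537). The smallest p of the exact two-sided permutation test was 0.10, the least that 3 against 3 samples allow. An exact permutation test of F over the 3 groups (1680 splits) gave an unadjusted p of 0.025 for cycling cells and 0.0429 for Schwann cells, and 0 classes passed after adjustment. Without GF 3, 1 class passed for SPF against HFA.

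The clusters that held a class are given with cells pooled per group, and samples within a group differed. Of GF progenitors, 32.0% lay in cluster 10, 23.0% in cluster 4 and 20.7% in cluster 8, and SPF progenitors lay in the same clusters, with 29.0%, 27.5% and 26.8% (1.29%, 6.81% and 55.2% in SPF 3). HFA progenitors were led by cluster 15 (23.5%), of which 99.0% came from HFA 2, then cluster 4 (20.9%) and cluster 9 (14.5%), of which 95.3% came from HFA 1. Adipocytes of GF and HFA were mostly in cluster 19, with 80.2% and 70.3%. In HFA, 26.0% were in cluster 33, which held 96.8% of the adipocytes of HFA 2. SPF adipocytes were in cluster 17 (44.8%) and cluster 16 (42.9%), and cluster 16 held 91.0% of the adipocytes of SPF 3 (Wilson 95% interval 90.1% to 91.9%). Endothelial cells shared clusters 0, 1 and 3 across the groups, led in the pooled cells by cluster 1 in GF (40.6%) and by cluster 0 in HFA (45.6%) and SPF (53.1%). This did not hold in each sample: GF 2 was led by cluster 0 (37.1%, against 33.1% in cluster 1) and HFA 1 by cluster 1 (52.5%, against 34.0% in cluster 0).

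**Figure D2:**
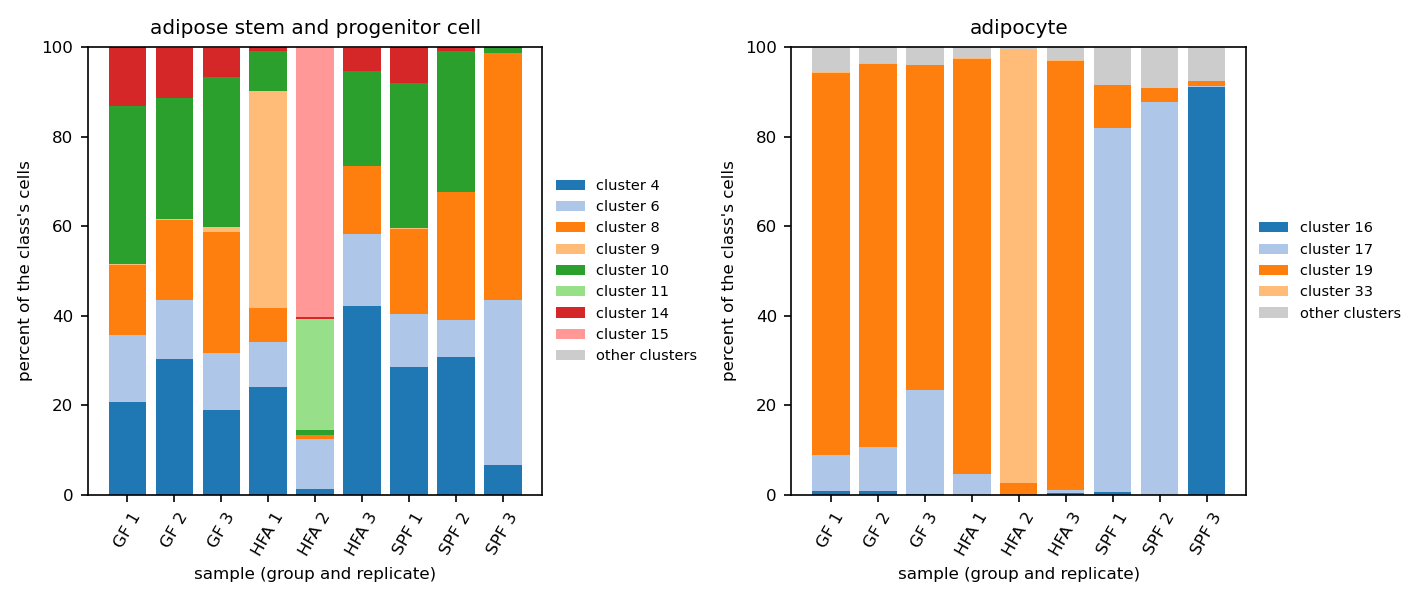
Percent of the progenitors and of the adipocytes of each sample that lie in each cluster. Cluster 33 holds 96.8% of the adipocytes of HFA 2, and cluster 16 holds 91.0% of those of SPF 3.

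Among unnamed clusters, cluster 5, with few UMIs per cell and both progenitor and adipocyte markers, held 6.44% ± 1.03 of GF, 2.30% ± 1.79 of HFA and 6.05% ± 4.18 of SPF cells. Cluster 7 held 0.0312%, 0.00931% and 8.91%, cluster 18 held 0.594%, 0.532% and 1.17%, and cluster 29 held 1.04%, 0.532% and 0.156% in that order. Cluster 26 held 0.640%, 0.183% and 0.181%, cluster 21 held 0.0894%, 0.0208% and 0.0289%, and cluster 20 held 0%, 0% and 0.0353%.

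SPF was compared with GF to see how fat of pigs with microbes but no listed pathogens differs from that of pigs without microbes. In progenitors, BPHL (ENSSSCG00000001008), a serine hydrolase, rose from 6.76 ± 1.68 to 25.8 ± 3.10 CPM in SPF (n = 3 each), a log2 fold change of 1.93 ± 0.21 (adjusted p = 0.0269). GPR176 (ENSSSCG00000004787), an orphan G protein-coupled receptor, fell from 180 ± 4.42 to 84.8 ± 1.61 CPM (-1.09 ± 0.11, adjusted p = 0.0269). ELAPOR2 fell from 37.1 ± 5.11 to 11.0 ± 2.16 CPM (-1.74 ± 0.20, adjusted p = 0.0269), CEMIP2, a hyaluronidase of the cell surface, fell by 1.10 ± 0.14 (adjusted p = 0.0356) and NEK11, a kinase of the DNA damage response, fell by 0.93 ± 0.14 (adjusted p = 0.0493). In each of these genes every SPF sample lay apart from every GF sample.

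The list with the largest count of changed members was that of ribosomal proteins, the protein part of ribosomes. It was a small part of all UMIs in both groups. It took 0.260% ± 0.037 of UMIs in GF and 0.553% ± 0.068 in SPF progenitors. The means were 0.227% and 0.397% in adipocytes, and 0.382% and 1.06% in endothelial cells. In progenitors its median log2 fold change was 1.14, 15 of 53 members rose over all genes tested, and 50 rose when adjusted over the list alone. RPL7 rose by 1.63 ± 0.24 (adjusted p = 0.0493) and RPL6 by 1.26 (adjusted p = 0.0269). In adipocytes the median was 0.98 (30 rose over all genes, 49 adjusted over the list alone), and in endothelial cells it was 1.51 (40 and all 53). Camera called the list in the 3 classes at the preset correlation. The adjusted p = 0.227 in progenitors, 0.117 in adipocytes and 0.387 in endothelial cells with an estimated correlation. HBB, the haemoglobin beta chain made by red cells, moved the same way. It stood at 34.5, 29.5 and 188 CPM in GF, HFA and SPF progenitors, 18.9, 16.3 and 98.5 CPM in adipocytes, and 79.5, 65.6 and 564 CPM in endothelial cells. The SPF minus GF log2 fold changes of HBB were 2.43 ± 0.64 (adjusted p = 0.169), 2.37 ± 0.50 (adjusted p = 0.107) and 2.86 ± 0.55 (adjusted p = 0.0371).

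**Figure D3:**
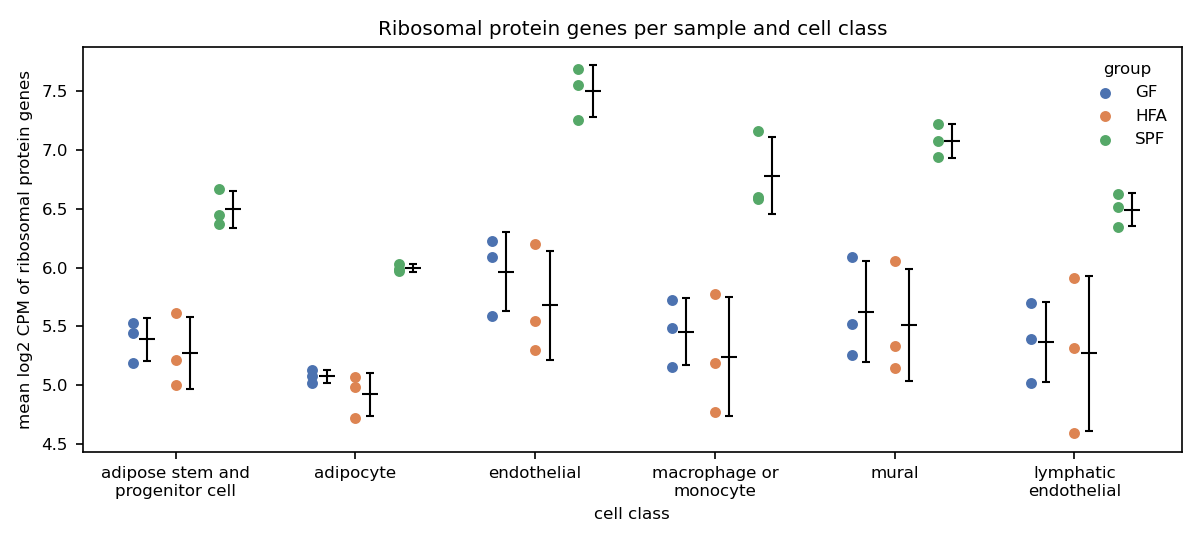
Mean log2 CPM of the ribosomal protein genes per sample in 6 cell classes (points, samples; bars, group mean ± SD). The median log2 fold change of the list, SPF minus GF, is 1.14 in progenitors, 0.98 in adipocytes and 1.51 in endothelial cells.

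Other lists in progenitors were called by camera at the preset correlation, with few members past the threshold. Nuclear-encoded oxidative phosphorylation had a median of 0.48 and 51 of 56 members higher in SPF. Of these, 1 rose over all genes (NDUFB9, a subunit of respiratory complex I, 1.09 ± 0.17, adjusted p = 0.0493) and 5 adjusted over the list alone. Adipogenic genes (median 0.54), mitochondrially encoded proteins (0.65), MHC class I presentation (0.67), MHC class II presentation (0.63) and heat shock genes (0.27) had 0 members past the threshold over all genes, and 1, 0, 1, 3 and 0 adjusted over the list alone. All 6 of these lists had an adjusted p = 0.861 with an estimated correlation. TGF-beta and BMP signalling was lower in SPF (median -0.36, 21 of 25 members), with adjusted p = 0.227 with an estimated correlation. CD74, the invariant chain of MHC class II, was at 85.1 CPM in GF and 166 CPM in SPF (0.96 ± 0.16, adjusted p = 0.0531). Cluster 18, unnamed with dendritic cells as its best match, held 0.594% of GF and 1.17% of SPF cells. RNA of such cells was not set apart from a change in progenitors.

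In adipocytes, GSTO2 (ENSSSCG00000030271), a glutathione transferase, rose from 0.805 to 8.81 ± 3.27 CPM (3.43 ± 0.43, adjusted p = 0.0199), and KCTD4 from 19.6 to 82.7 CPM (2.07 ± 0.34, adjusted p = 0.0422). MAPK12, a p38 kinase, rose by 2.63 ± 0.44 (adjusted p = 0.0435), as did the interferon alpha gene IFN-ALPHA-15 (2.74 ± 0.30, adjusted p = 0.0171), a member of a gene family of near-identical copies. CX3CR1, the fractalkine receptor known from monocytes and macrophages, rose from 0.341 to 2.02 CPM (2.54 ± 0.43, adjusted p = 0.0435), while macrophages took 8.27% of GF and 4.56% of SPF cells. OTOF, a calcium sensor of vesicle fusion, fell from 5.09 to 0.358 CPM (-3.83 ± 0.44, adjusted p = 0.0178), SLC47A2, a cation exporter, fell by 4.73 ± 0.56 (adjusted p = 0.0181) and TRIM36, a ubiquitin ligase, fell by 2.02 ± 0.34 (adjusted p = 0.0435). CD74 rose from 63.3 ± 3.81 to 102 ± 3.37 CPM (0.68 ± 0.12, adjusted p = 0.0451). It was the 1 member of 10 in MHC class II presentation past the threshold (3 adjusted over the list alone, median 0.57), a list with adjusted p = 0.574 with an estimated correlation. Cluster 18 held 0.594% of GF and 1.17% of SPF cells, while the share of macrophages was lower in SPF. RNA of such cells was not set apart from a change in adipocytes. MHC class I presentation (median 0.31), oxidative phosphorylation (0.35), mitochondrially encoded proteins (0.54) and TGF-beta and BMP signalling (-0.26) were also called at the preset correlation. They had 0, 1 (NDUFB9, 1.08 ± 0.17, adjusted p = 0.0395), 0 and 0 members past the threshold over all genes, and 3, 2, 0 and 0 adjusted over the list alone. Their values were adjusted p = 0.830, 0.853, 0.853 and 0.574 with an estimated correlation.

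In endothelial cells, WHRN (ENSSSCG00000005490), the scaffold protein whirlin, rose from 0.959 ± 0.519 to 104 ± 24.1 CPM (6.74 ± 0.34, adjusted p = 2.59e-05), while HFA was at 1.30 CPM. In progenitors WHRN stood at 11.7, 16.9 and 8.86 CPM in GF, HFA and SPF. FMO2, a flavin monooxygenase (2.62 ± 0.49, adjusted p = 0.0321), and MOGAT2, an enzyme of triglyceride synthesis (2.65 ± 0.51, adjusted p = 0.0365), rose too. FMO2 was among the leading genes of progenitor cluster 4 and MOGAT2 among those of adipocyte cluster 17. Of 29 markers of other classes in endothelial cells, the median log2 fold change was 0.54 ± 0.64 (SD over the markers). Past the threshold were DPT (1.76, adjusted p = 0.0243), PDGFRA (1.97, adjusted p = 0.0423) and the adipocyte marker CIDEC (1.63, adjusted p = 0.0423). RNA of other classes was thus not set apart from endothelial changes here. CCL5, a T cell chemokine (2.89 ± 0.35, adjusted p = 0.0117), and GNLY, a protein of cytotoxic lymphocytes (2.68 ± 0.53, adjusted p = 0.0392), rose, with T or NK cells at 0.875% of GF and 1.40% of SPF cells. ADAMTS18, a secreted protease, fell from 243 to 67.4 CPM (-1.85 ± 0.23, adjusted p = 0.0117), DOK5 fell by 2.42 ± 0.49 (adjusted p = 0.0422), TRAF5, a TNF receptor adaptor, fell by 1.88 ± 0.28 (adjusted p = 0.0190), CKAP2, a mitotic protein, fell by 1.86 ± 0.41 (adjusted p = 0.0487), and CYP2J34, a cytochrome P450, fell by 1.82 ± 0.31 (adjusted p = 0.0251).

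Camera called 11 lists in endothelial cells, all higher in SPF at the preset correlation. Adipogenic genes had a median of 0.98. FABP5, a fatty acid carrier (1.57 ± 0.31, adjusted p = 0.0365), and CIDEC, a lipid droplet protein (1.63 ± 0.33, adjusted p = 0.0423), rose over all genes. CIDEC is also one of the markers of other classes given above. Adjusted over the list alone, 11 of 23 members rose and 1 fell (adjusted p = 0.444 with an estimated correlation). Adipocytes made up 19.5% of GF and 27.0% of SPF cells. Oxidative phosphorylation had a median of 0.76, with 3 members past the threshold, NDUFS5 (1.30), UQCRQ (1.31) and COX5A (0.58), and 24 of 56 adjusted over the list alone (adjusted p = 0.444 with an estimated correlation). In the type I interferon response, TRIM25, which activates RNA sensing (1.37, adjusted p = 0.0221), and ISG12(A) (1.22, adjusted p = 0.0283) rose, and 3 of 35 adjusted over the list alone (median 0.23, adjusted p = 0.511 with an estimated correlation). In MHC class I presentation and interferon gamma response, GBP2, an interferon-induced GTPase (1.93, adjusted p = 0.0423), and SOCS1, a brake on cytokine signalling (2.04, adjusted p = 0.0449), rose, and 5 of 15 adjusted over the list alone (median 0.62, adjusted p = 0.440 with an estimated correlation). The lipid-associated macrophage (median 0.92), heat shock (0.56), immediate early (0.61), lymphocyte (0.97), cholesterol (0.30) and lipolysis (0.26) lists had 1, 0, 0, 2, 1 and 0 members past the threshold over all genes, and 7, 7, 0, 2, 3 and 2 adjusted over the list alone. Their values were adjusted p = 0.511, 0.440, 0.699, 0.387, 0.641 and 0.641 with an estimated correlation.

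**Figure D4:**
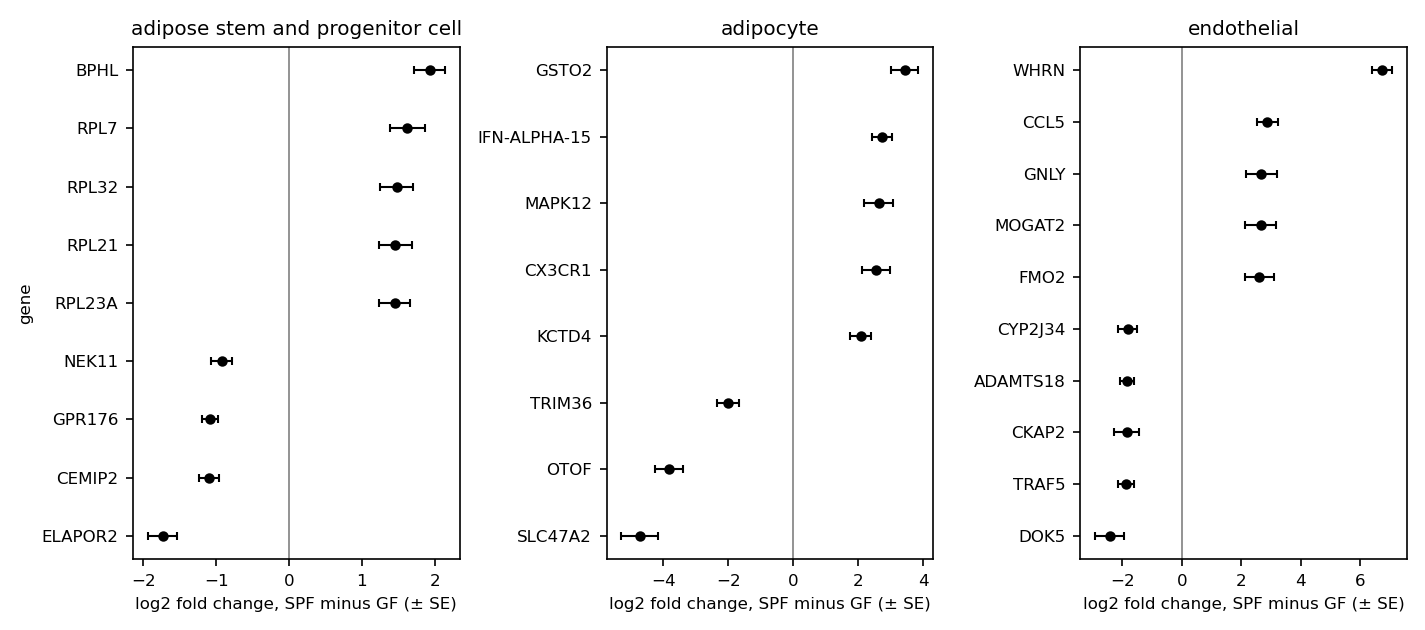
Log2 fold change ± SE, SPF minus GF, of the named genes with the largest rise or fall in progenitors, adipocytes and endothelial cells. WHRN in endothelial cells, at 6.74, has the largest value.

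Over all genes, edgeR called 34 of 14554 in progenitors (30 higher and 4 lower in SPF), 78 of 14489 in adipocytes (74 and 4) and 239 of 11546 in endothelial cells (176 and 63). The groups did not overlap in 22.7%, 18.6% and 25.0% of genes, against the 10% that chance gives. The progenitor count was 0 without GF 1, GF 2, SPF 2 or SPF 3, 1 without SPF 1, 2 without GF 3, 10 without HFA 3, 86 without HFA 2 and 92 without HFA 1. With the replicate number as a block it was 75. The adipocyte count was 0 without GF 1, GF 2, GF 3, SPF 1 or SPF 2, 31 without HFA 3 and 35 without SPF 3, and with that block it was 1, with 0 of the 78 kept. Without both HFA 2 and SPF 3, the counts were 0 in progenitors and 0 in adipocytes. With cluster 7 counted among the progenitors theirs was 11 (11 of the 34 kept). It was 59 with DESeq2 size factors, 62 with no filter, 65 with the strict cell filter, 55 with classes from resolution 2.0 and 115 with only the 6 samples compared. With doublets kept the endothelial count was 104 (99 of the 239 kept), and the DESeq2 Wald test called 480, 479 and 641 genes in the 3 classes. The endothelial count was 23, 11 and 42 without GF 1, GF 2 or GF 3, 143 without HFA 3, and 44, 95 and 32 without SPF 1, SPF 2 or SPF 3.

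HFA was compared with GF to see what goes with human-derived microbes. No gene passed the threshold in any main class. In adipocytes the smallest p values belonged to SHROOM2, an actin regulator, at 2.87 CPM in GF and 12.3 CPM in HFA (2.09 ± 0.24, adjusted p = 0.105), FAM155B (2.92 ± 0.35, adjusted p = 0.105) and SLC47A2 (-3.75 ± 0.52, adjusted p = 0.229). In progenitors they belonged to ANK1, a membrane skeleton protein, at 24.0 ± 5.59 and 4.80 ± 2.45 CPM (-2.32 ± 0.38), EGFLAM, a matrix protein (1.29 ± 0.21), and CRYGS, a crystallin (-1.40 ± 0.24), each with adjusted p = 0.469. In endothelial cells they belonged to EDA, the TNF family ligand ectodysplasin, at 59.7 and 166 CPM (1.47 ± 0.20, adjusted p = 0.334), CCDC68 (1.07 ± 0.16, adjusted p = 0.350) and STK17A, a kinase (-0.92 ± 0.16, adjusted p = 0.473).

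Fatty acid and triglyceride synthesis was higher in HFA in the 3 main classes by camera at the preset correlation, with medians of 0.30 in progenitors, 0.57 in adipocytes and 0.36 in endothelial cells. In adipocytes FASN, the fatty acid synthase, was at 365 CPM in GF and 987 CPM in HFA (1.44 ± 0.52, adjusted p = 0.556), with 528, 1434 and 1000 CPM in HFA 1, HFA 2 and HFA 3. The adjusted p = 0.907, 0.565 and 0.750 with an estimated correlation, and 0, 0 and 2 of the members passed adjusted over the list alone. In each of the 3 classes the call ended without HFA 2 and without GF 1: the adjusted p of the list of fatty acid and triglyceride synthesis in adipocyte, HFA against GF, was then 0.423 and 0.0722. It also ended without HFA 3 in progenitors and endothelial cells. Complement was lower in HFA in all 3 (medians -0.48, -0.42 and -0.47), with 0, 2 and 1 members lower adjusted over the list alone, and adjusted p = 0.907, 0.511 and 0.750 with an estimated correlation. CLU, an extracellular chaperone of that list, was at -1.59 in adipocytes (adjusted p = 0.453) and -1.56 in endothelial cells (adjusted p = 0.473).

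Further lists were called at the preset correlation in 1 or more classes, with 0 members past the threshold over all genes. In progenitors these were DPP4-type progenitor genes (-0.36), cholesterol synthesis (0.22), oxidative phosphorylation (0.18), mitochondrially encoded proteins (0.57), resident macrophage genes (-0.32), immediate early genes (0.49) and skeletal muscle genes (4.06), each with adjusted p = 0.907 with an estimated correlation. The adjusted p of the list of immediate early and dissociation response in adipose stem and progenitor cell, HFA against GF, was 0.0223 with all samples and 0.522 without HFA 3, where its sign turned. Adjusted over the list alone, 1 DPP4-type gene was lower, 5 of 6 muscle genes were higher, and 0 members of the others passed. The skeletal muscle genes stood at 2091 CPM in progenitors of HFA 2, which held 484 of the 485 muscle cells. In adipocytes they were oxidative phosphorylation (0.15, adjusted p = 0.577 with an estimated correlation), collagens (-0.32), immediate early genes (-0.57) and ribosomal proteins (-0.15), each 0.565, and NF-kB response (-0.19) and resident macrophage genes (-0.38), both 0.511. In endothelial cells they were DPP4-type genes (-0.42), collagens (-0.41) and heat shock genes (-0.33), each with adjusted p = 0.750 with an estimated correlation, and ribosomal proteins (-0.25, adjusted p = 0.890).

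EdgeR called 0 genes in each main class, with 1060, 1230 and 731 genes at an unadjusted p under 0.05 in progenitors, adipocytes and endothelial cells. Limma voom called 0 in each and DESeq2 called 59, 80 and 27. The groups did not overlap in 12.8%, 15.5% and 11.5% of genes, where chance gives 10%. Without HFA 1, 1 gene was called in adipocytes.

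SPF was compared with HFA to set pigs with microbes but no listed pathogens beside pigs with human-derived microbes. In progenitors PTH2R, a receptor of the parathyroid hormone family (4.07 ± 0.56, adjusted p = 0.0275), ADIRF, a promoter of adipogenesis (2.90 ± 0.43, adjusted p = 0.0299), and BMP7, a growth factor of adipose differentiation (27.7 to 98.1 CPM, 1.82 ± 0.29, adjusted p = 0.0415), rose in SPF. At resolution 2.0, BMP7 was a leading gene of a progenitor cluster that shared the leading genes WNT2 and SEMA3C with cluster 8. Cluster 8 held 7.41% of HFA progenitors (0.831% to 15.4% per sample) and 26.8% of SPF progenitors (19.0% to 55.2%). Whether BMP7 rose within such a cluster was not tested. CD74 rose by 1.28 ± 0.17 (adjusted p = 0.0269). LOXL2, a collagen cross-linking enzyme, fell from 331 to 150 CPM (-1.14 ± 0.16, adjusted p = 0.0275), COL13A1, a transmembrane collagen, fell by 2.97 ± 0.48 (adjusted p = 0.0409), EGFLAM fell by 1.95 ± 0.22 (adjusted p = 0.0192), ERRFI1, an inhibitor of the EGF receptor, fell by 2.07 ± 0.26 (adjusted p = 0.0269), and TSPAN15 fell by 2.02 (adjusted p = 0.0446).

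In adipocytes, GSTO2 (3.97 ± 0.44, adjusted p = 0.00854), EPHA3, an ephrin receptor (2.71 ± 0.47, adjusted p = 0.0404), NLGN1, a cell adhesion protein (2.53 ± 0.40, adjusted p = 0.0289), CDO1, an enzyme of cysteine breakdown (2.25 ± 0.37, adjusted p = 0.0317), and CD74 (1.03 ± 0.12, adjusted p = 0.00923) rose. UTS2B, a peptide of the urotensin family, was at 0 CPM in GF and HFA and 1.42 ± 0.521 CPM in SPF. OTOF (-4.90 ± 0.45), FAM155B (-3.22 ± 0.34), C3orf85 (-2.72), KIF12, a kinesin (-2.32), and TRIM36 (-2.04) fell, with adjusted p = 0.00729, 0.00729, 0.0387, 0.0493 and 0.0351.

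In endothelial cells WHRN rose by 6.24 ± 0.32 (adjusted p = 2.91e-05), GNLY by 3.25 (adjusted p = 0.0224), CCL5 by 1.99 (adjusted p = 0.0182), CA3, a carbonic anhydrase, by 2.67 (adjusted p = 0.0228), and PLIN1, a lipid droplet coat protein, by 1.27 (adjusted p = 0.0312). T or NK cells were at 0.542% of HFA and 1.40% of SPF cells. HSP70.2, a chaperone, rose from 15.8 to 296 ± 340 CPM (4.18 ± 0.85, adjusted p = 0.042). CD74 (1.10, adjusted p = 0.0352), B2M, the light chain of MHC class I (1.31, adjusted p = 0.042), and IFIT1, an interferon-induced protein (2.03, adjusted p = 0.0262), rose. The cell cycle regulators E2F8 (-2.53, adjusted p = 0.0292), TICRR (-2.12, adjusted p = 0.0441) and FBXO5 (-1.81, adjusted p = 0.0274), with ZBTB7C (-1.83, adjusted p = 0.033) and DIAPH3, a formin (-1.74 ± 0.23, adjusted p = 0.0099), fell. Cycling cells, a class of their own, were at 1.94% of HFA and 0.692% of SPF cells.

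Ribosomal protein genes had medians of 1.27, 1.13 and 1.81 in progenitors, adipocytes and endothelial cells. Of 53 members, 30, 39 and 50 rose over all genes and 51, 48 and 52 adjusted over the list alone. HBB was at 29.5, 16.3 and 65.6 CPM in HFA and 188, 98.5 and 564 CPM in SPF in those classes. With an estimated correlation the list had adjusted p = 0.432, 0.147 and 0.289. MHC class II presentation was higher in SPF progenitors (0.79, 1 member over all genes and 2 of 12 adjusted over the list alone) and adipocytes (0.97, 1 and 5 of 10), with adjusted p = 0.744 and 0.698 with an estimated correlation. Cluster 18 held 0.532% of HFA and 1.17% of SPF cells. RNA of such cells was not set apart from these rises or from those of CD74 in the main classes. MHC class I presentation had medians of 0.79, 0.64 and 0.52, with 0, 0 and 1 members over all genes and 1, 3 and 5 adjusted over the list alone (adjusted p = 0.744, 0.763 and 0.363 with an estimated correlation). Heat shock genes had medians of 0.51, 0.24 and 0.84. In endothelial cells HSPA8 (1.42), HSP90AB1 (1.42), HSPB1 (1.55) and HSP70.2 rose over all genes, and 13 of 21 adjusted over the list alone. In progenitors 8 rose and 1 fell, and in adipocytes 1 rose, adjusted over the list alone. The list had adjusted p = 0.457, 0.763 and 0.289 with an estimated correlation.

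The remaining lists called at the preset correlation were mostly in endothelial cells. Adipogenic genes had a median of 0.60 in progenitors (1 over all genes, ADIRF, and 1 adjusted over the list alone) and 1.07 in endothelial cells (2, and 12 of 23), with adjusted p = 0.744 and 0.363 with an estimated correlation, while adipocytes were at 22.6% of HFA and 27.0% of SPF cells. Oxidative phosphorylation had medians of 0.30, 0.15 and 0.61, with 0, 0 and 2 members over all genes and 0, 0 and 15 adjusted over the list alone (adjusted p = 0.968, 0.799 and 0.401 with an estimated correlation). In progenitors DPP4-type genes (0.61), type I interferon response (0.29), lipid-associated macrophage genes (0.33) and TGF-beta and BMP signalling (-0.28, in which BMP7 rose) had 1, 0, 0 and 1 members past the threshold over all genes, and 3, 0, 0 and 1 adjusted over the list alone. Their values were adjusted p = 0.457, 0.984, 0.984 and 0.432 with an estimated correlation. In endothelial cells cholesterol synthesis (0.42), type I interferon response (0.11), lipid-associated macrophage genes (0.67), complement (0.80), lymphocyte genes (0.35), glucocorticoid response (0.37) and immediate early genes (0.72) had 0, 1, 0, 0, 2, 0 and 0 members over all genes, and 0, 5, 7, 2, 2, 0 and 3 adjusted over the list alone. Their values were adjusted p = 0.568, 0.573, 0.363, 0.363, 0.363, 0.573 and 0.393 with an estimated correlation. Cell cycle genes were lower in SPF (-0.62, 14 of 17 members), with 1 member higher over all genes, 1 higher and 3 lower adjusted over the list alone, and adjusted p = 0.571 with an estimated correlation, while cycling cells were at 1.94% of HFA and 0.692% of SPF cells.

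EdgeR called 72 genes in progenitors (62 higher and 10 lower in SPF), 116 in adipocytes (102 and 14) and 213 in endothelial cells (181 and 32). The groups did not overlap in 19.6%, 19.7% and 21.9% of genes, where chance gives 10%. The progenitor count was 37 without GF 1, 0 without GF 2, 1 without GF 3, 9 without HFA 1, and 0 without HFA 3, SPF 1, SPF 2 or SPF 3. The adipocyte count was 73, 64 and 69 without GF 1, GF 2 or GF 3, 53 without HFA 2, 34 without HFA 3, 23 without SPF 1 and 18 without SPF 2. The endothelial count was 128 without GF 2, 86 without HFA 1, 1 without HFA 3, and 47 and 95 without SPF 1 or SPF 2. With only the 6 samples compared, the counts were 0 in progenitors, 0 in adipocytes and 103 in endothelial cells (94 of the 213 kept). Without both HFA 2 and SPF 3 they were 41 in progenitors and 0 in adipocytes. With cluster 7 counted the progenitor count was 40 (38 of the 72 kept), with the replicate number as a block the adipocyte count was 75 (69 of the 116 kept), and with doublets kept the endothelial count was 123 (119 of the 213 kept). The DESeq2 Wald test called 570, 739 and 502.

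In mural cells edgeR called 77 genes for SPF against GF (60 higher and 17 lower) and 82 for SPF against HFA (62 and 20). BPHL was higher in SPF than in GF there too (2.21 ± 0.27, adjusted p = 0.0145), as was EYA4, a transcriptional coactivator (2.51 ± 0.25, adjusted p = 0.00668), and SNTG1, a syntrophin, was lower (-4.90 ± 0.53, adjusted p = 0.00918). For HFA against GF, edgeR called 0 genes in mural cells, with 405 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by voom. In macrophages edgeR called 0 in each comparison, with 615, 1245 and 1147 genes at an unadjusted p under 0.05 for HFA against GF, SPF against GF and SPF against HFA. DESeq2 called 9, 205 and 187 there, and voom 0, 10 and 0. In lymphatic endothelial cells edgeR called 0, with 441, 1012 and 1196 at an unadjusted p under 0.05, 4, 95 and 180 by DESeq2, and 0, 1 and 0 by voom. Cycling cells had 9 genes past the threshold for SPF against HFA. Ribosomal proteins were higher in SPF there (median 1.19, 51 of 52 members), and the list passed at the preset correlation, by fry (adjusted p = 0.00253) and at adjusted p = 0.0465 with an estimated correlation.

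With all cells of a sample summed, edgeR called 0 genes for HFA against GF, 47 for SPF against GF (44 higher and 3 lower) and 96 for SPF against HFA (83 and 13), of 16422 tested. For HFA against GF, 1120 genes had an unadjusted p under 0.05, DESeq2 called 97 and voom 0, and edgeR called 1 without HFA 1 and 2 without HFA 3. The count for SPF against GF was 0 without any 1 of the GF or SPF samples, 1 without HFA 3, 97 without HFA 2 and 137 without HFA 1. That for SPF against HFA was 0 without any 1 of the GF or SPF samples or HFA 3, and 14 without HFA 1. It was 158 with the replicate number as a block and 0 with only the 6 samples compared. For SPF against GF it was 0 without both HFA 2 and SPF 3, 94 with the block, 173 with only the 6 samples, 10 with no filter, 83 with the strict cell filter and 83 by voom. The DESeq2 Wald test called 1020 for SPF against GF and 1192 for SPF against HFA.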

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

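The tests of mesothelial cells, of muscle RNA in every droplet, with the clusters of resolution 2.0 tried last, and of an equal number of free UMIs were chosen only after the results were seen, and the markers HBB and WT1 were taken up for the same reason. A cell group held mostly by 1 sample, not compared gene by gene and above its level in the GF samples, drew attention in 3 cases; of these, the shares of muscle and epithelial cells were tested and did not pass. Cluster 7 had 2762 of its 2788 cells in SPF 3 (26.6% of that sample) and at most 4 in a GF sample. Skeletal muscle cells numbered 484 in HFA 2 (4.81% of that sample), of 485 in all, and 0 in the GF samples. Epithelial cells numbered 195 in HFA 1 (3.09%), of 274 in all, against at most 43 in a GF sample; their leading genes included the keratins KRT25 and KRT71.

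Ribosomal protein genes were higher in SPF than in GF, with median log2 fold changes of 1.14 in progenitors, 0.98 in adipocytes and 1.51 in endothelial cells. A difference in UMIs per cell is argued against, since among cells of 1000 to 4000 UMIs the medians were 1.29, 1.49 and 1.61. In adipocytes that window held a small part of the cells (119 of 1320 in GF 1 and 143 of 1876 in SPF 2). The larger difference among cells of few UMIs is also what an equal number of free UMIs per droplet would give. Free RNA in every droplet stays open. Markers of other classes had medians of 0.076 ± 0.50, 0.15 ± 0.66 and 0.54 ± 0.64 (SD over the markers), below the bound set beforehand. That bound was wrong, because HBB, a red cell message that these classes should lack, was higher in SPF by 2.43, 2.37 and 2.86. The excess of ribosomal protein UMIs per cell differed 1.80-fold between the highest and lowest of 6 classes (1.45 to 2.38 with a sample left out), against 3.19-fold for UMIs per cell, which leaves an equal free amount open as well. More cytoplasmic RNA per droplet may contribute: the medians of oxidative phosphorylation genes were 0.48 ± 0.34 and 0.35 ± 0.29 in progenitors and adipocytes, which leave it open, and 0.76 ± 0.43 in endothelial cells, which reached the bound of 0.76 only just, and the microbial status of the pigs was not tested apart from these.

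SPF 3 held 91.0% of its adipocytes in a cluster of its own, and cluster 7, a group with progenitor markers, while 0 of its 1503 endothelial cells were in such clusters, at resolution 1.0 and at 2.0. Mesothelial cells are argued against as the source of cluster 7, though on few markers. WT1 had a UMI in 33.0% of the cells of cluster 7 (median 3522.5 UMIs) and in 0.798% of endothelial cells of SPF 3 (median 2081). The median over 4 other mesothelial markers was 0.0543%, and KRT8 was in 0 of 2762 cells against 36.5% in cluster 29. Cluster 29 is itself unnamed, with mesothelial as its best match on 2 markers. KRT8 was in 3 of 195 epithelial cells of HFA 1. CALB2 was in at most 0.704% of cells of any class and so could not decide. MSLN, UPK3B, KRT19 and LRRN4 were not among the features. Another fat depot may be the source and stays open. Subcutaneous patterning genes in progenitors of SPF 3, here 852 cells with the 2762 of cluster 7 added, had a median difference of -0.67 ± 1.33 (log2) from the other samples. Of these 7 genes, 4 (SHOX2, IRX2, HOXC10 and HOXC9) were below all of 7 other samples and EN1 was above them. The 7 patterning genes known to be higher in visceral fat had a median difference of 0.091. Of these, 0 were above the other samples and GATA5 was below them, so no rise of the visceral set was seen. The labels do not name the depot, so a difference between animals was not tested apart from it.

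HFA 2 held 85.1% of its progenitors, 96.8% of its adipocytes and 91.5% of its macrophages in clusters of its own, and carried 10.1 to 10.7 muscle UMIs per cell in each of 6 classes, against at most 0.287 in the other samples. Free muscle RNA in every droplet may be the cause and stays open, since it would reach endothelial cells too, and 0 of 1259 of these were in such clusters at resolution 1.0 (upper Wilson 95% limit 0.304%) but 810 (64.3%, 61.7% to 66.9%) at resolution 2.0, where mural cells stayed at 0 of 513 and lymphatic endothelial cells were at 31 of 401 (7.73%). The test chosen first, on the 100 genes raised most in its adipocytes, gave 43% that were higher in its muscle cells, which did not decide. Another fat depot may be the source and stays open, with a median absolute difference of 0.51 ± 0.63 in the subcutaneous patterning genes. Of these, 1 was below and 2 were above the other samples. Each of the visceral patterning genes lay within the range of the other samples, with differences from -0.50 (HOXA5) to 0.25 (NR2F1). No biological explanation was tested.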

How the results depend on the processing

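Leaving out HFA 2 and SPF 3 together, counting the WT1-led cluster with the progenitors, and DESeq2 size factors in the list tests were chosen after the clusters were seen. No call of a named gene turned direction under any alternative run. In each call every sample of 1 group lay above every sample of the other. A turn was thus hardly possible, and its absence carries little weight. Named genes that were not called are not covered. Of 109 calls of named genes, 109 were kept by the DESeq2 Wald test, 107 with DESeq2 size factors, 102 with the strict cell filter, 95 by voom, 54 with only the 6 samples compared, 32 without HFA 2 and SPF 3, and 27 without SPF 1. Of 76 list calls in the main classes, 76 were kept with DESeq2 size factors, 8 by fry and 0 with an estimated correlation. With samples left out in turn, the adjusted p of the list of immediate early and dissociation response in adipose stem and progenitor cell, HFA against GF, ran from 1.64e-05 without HFA 2 to 0.522 without HFA 3, where its sign turned, against 0.0223 with all. Of absolute log2 fold changes of 1 simulated for SPF against GF, 12% were found in progenitors, so changes of that size are mostly missed at this depth and number of samples. Except where fewer samples were fitted, the cause was not tested. Skeletal muscle gave no share test without HFA 2, since too few cells were left.

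In the order HFA against GF, SPF against GF and SPF against HFA, the DESeq2 Wald test called 59, 480 and 570 genes in progenitors, 80, 479 and 739 in adipocytes, 27, 641 and 502 in endothelial cells, and 97, 1020 and 1192 in all cells. For SPF against GF, progenitors gave 59 genes with DESeq2 size factors, 62 with no filter, 115 with only the 6 samples compared, 65 with the strict cell filter and 55 with classes from resolution 2.0. All cells gave 10 with no filter, 173 with only the 6 samples, 83 with the strict filter and 83 by voom. For SPF against HFA, only the 6 samples compared gave 0 in progenitors, adipocytes and all cells and 103 in endothelial cells. Doublets kept gave 104 and 123 in endothelial cells for SPF against GF and against HFA. Without both HFA 2 and SPF 3, progenitors gave 1, 0 and 41 genes in the order above, adipocytes 0 for SPF against GF and 0 for SPF against HFA, and all cells 0 for SPF against GF. The WT1-led cluster counted with the progenitors gave 11 for SPF against GF and 40 for SPF against HFA, and 1 class share for SPF against HFA, as did classes from resolution 2.0 and TMM factors over classes.

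With each sample left out in turn, gene counts in that order ran from 0 to 0, 0 to 92 and 0 to 91 in progenitors, 0 to 1, 0 to 112 and 18 to 143 in adipocytes, 0 to 0, 11 to 339 and 1 to 199 in endothelial cells, and 0 to 2, 0 to 137 and 0 to 86 in all cells. Shares passed in 0 classes, and in 0 to 1 for SPF against HFA (1 without GF 3). List counts ran from 3 to 9, 3 to 11 and 8 to 14 in progenitors, 6 to 17, 2 to 10 and 3 to 9 in adipocytes, and 4 to 9, 10 to 16 and 11 to 14 in endothelial cells. In progenitors they were 5 without HFA 1 and 3 without HFA 3 (9 with all, HFA against GF), and 3 without GF 1 and 5 without SPF 2 (8 with all, SPF against GF). In adipocytes they were 17 without GF 2 (8 with all, HFA against GF), 2 without GF 1 and 10 without SPF 1 (6 with all, SPF against GF), and 9 without HFA 3 and 3 without SPF 2 (5 with all, SPF against HFA). With an estimated correlation, 0 lists passed in each main class and comparison. Fry called 0, 1 and 1 in progenitors, 0, 1 and 1 in adipocytes, and 0, 2 and 2 in endothelial cells. Equal cell numbers gave 4 in progenitors for HFA against GF, and leaving out HFA 2 and SPF 3 gave 5 and 9 in adipocytes for HFA against GF and SPF against HFA.

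With the replicate number as a block, 75 genes were called in progenitors and 1 in adipocytes for SPF against GF, 75 in adipocytes for SPF against HFA, and 94 and 158 in all cells for these comparisons, and 1 class share passed for SPF against HFA. Whether the numbers pair the samples is open: no label gives a shared animal, litter or batch, and the titles number the samples otherwise. Correlations of same-number samples across groups ran from -0.0934 to 0.318. Each of the 3 was over 0.1 in progenitors for SPF against GF (0.198, 0.116 and 0.122) and in all cells for SPF against HFA (0.187, 0.111 and 0.318) but not in the other 10 sets of 3. The best correlation was with the same number in 7 of 9 pairs in progenitors, 7 in adipocytes, 6 in endothelial cells and 6 in all cells. Chance matching among the 3 samples of a group would give fewer. The counts of the classes and of all cells reuse the same 9 samples and are not separate. GF 1 and HFA 1 also had the fewest kept cells (7278 and 6318) and the lowest mitochondrial percent of their groups, unlike SPF 1. Such likeness was not set apart from pairing. The matches are a hint of pairing from the data and not from the design, and pairing was not tested.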

Other observations

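All tests in this part were planned. Transcripts of the Y-linked genes EIF1AY, KDM5D and ZFY were present in each of the 9 samples, EIF1AY at 52.5 to 80.4 CPM, KDM5D at 68.9 to 136.9 CPM and ZFY at 138.5 to 197.4 CPM, while SRY had 0 counts.

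Each set of 6 samples can be parted into 3 and 3 in 10 ways, which are too few for a share under 0.05. For genes in SPF against GF, 1 of the 10 splits, the real one, reached its count in progenitors (34), adipocytes (78), endothelial cells (239) and all cells (47), and the highest other split had 0 in each. For SPF against HFA, again 1 split reached the counts of 72, 116, 213 and 96, and the highest other had 1, 0, 0 and 0. For HFA against GF, all 10 splits had 0 calls in the 4 sets, as the real split did.

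The list counts did not single out the real split. For HFA against GF, 6 of 10 splits reached the real 9 lists in progenitors (highest other 20), 4 reached 8 in adipocytes (highest other 11) and 8 reached 6 in endothelial cells (highest other 15). For SPF against GF, 6 splits reached 8 in progenitors (highest other 10), 7 reached 6 in adipocytes (highest other 12) and 5 reached 11 in endothelial cells (highest other 13). For SPF against HFA, 5 reached 10 (highest other 15), 9 reached 5 (highest other 12) and 2 reached 13 (highest other 13). The split with 20 lists set GF 1, HFA 1 and HFA 3 against GF 2, GF 3 and HFA 2 (9 lists in adipocytes and 15, the highest, in endothelial cells). The split with 11 in adipocytes set GF 1, HFA 1 and HFA 2 against the others.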
